A study of Homo sapiens with 32 samples.

How the data were processed

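Gene levels were measured in lysates of HepG2 cells by TempO-Seq, per the labels' protocols. The deposited table held 1 value per gene symbol for 13133 genes in 32 libraries. Its signal values were normalized by the authors, and the values themselves show how. Every deposited signal value was a whole number of reads divided by 1 factor per library (100% of values within a tolerance of 0.01 reads). The factors equalled median-of-ratios size factors recomputed over the 32 libraries, with a largest deviation of 2.2e-14 percent. The aligner, the counting, the genome build and the way probes were combined to genes are not given in the sources used here. The design had assumed raw counts or values per probe, so the test for normalized signal was used and the choice among probes did not apply.

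The signal values were taken to log2 after adding 1, and limma was fitted to these log2 values made from the deposited table. Genes with a mean of at least 5 over all libraries were tested, 9324 genes, and 3809 genes below that were left out. Libraries were grouped by exposure and time as the labels give them, 8 groups of 3 and 4 groups of 2. limma (3.58.1, in R 4.3.3) fitted 12 group means with an intensity trend and robust moderation, 20 residual degrees of freedom and a median prior of 13. Each coating was compared with NoNP at the same time, and coatings were compared with each other at each time, by an F test and in pairs. NoNP was compared between times, each coating was averaged over times, and the interaction of exposure and time was tested by F. P-values were adjusted by Benjamini-Hochberg over the tested genes within each comparison, with a threshold of 0.05. Counts at an unadjusted p under 0.05 are given beside some results. Chance alone gives a share near 0.05 of the 9324 tested genes there. edgeR (4.0.16) quasi-likelihood tests on the reads recovered from the values served as a second test, with a common biological coefficient of variation of 0.35.

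Gene lists, 30 in number, were fixed from general knowledge before the data were examined, as were the design, the comparisons, the alternatives and the rule for naming genes. The 29 lists with at least 3 tested members were tested by camera with a preset correlation of 0.01, and also with an estimated correlation and by fry. Camera p-values were adjusted over all lists and the 9 comparisons of a coating with NoNP together. They were adjusted separately over the 3 averages and over the 3 comparisons of NoNP between times. Member counts are given at the threshold over all genes and adjusted over the list alone.

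The genes named for a coating at 1 time came from the 10 largest rises and the 10 largest falls among genes past the threshold in which every treated library lay beyond every control library. Where fewer than 5 qualified, the 5 genes with the smallest p were given as values. Up to 4 members with the smallest p were open to naming in each list, the 10 genes with the smallest p for the differences among coatings and the interaction, and the 5 largest rises and 5 largest falls for NoNP over time. Genes outside this rule are marked where they appear. A group with 0 reads was set at 3 reads over the group, and folds against it are lower bounds. These bounds take a deposited 0 as 0 reads, and whether low counts were removed before the deposit is not given in the sources used here. Ratios to groups with 1 to 3 reads carry a 95% counting interval. A count of 0 in 1 library allows up to 1.382 to 7.148 normalized reads, depending on its depth of 1313855 to 6735072 reads.

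Fold changes against shared controls were compared with 100 simulated sets of unchanged groups that shared simulated controls. The fits were tested on simulated data with the depths of the real libraries and 1 spread per gene, the same in all groups. The wider spread of the 24 h controls (2.7 times the mean residual variance) was not simulated. The simulated counts for 24 h therefore do not measure false calls there. With 3 libraries against 3, limma recovered 27% of genes changed 2-fold and 67% of genes changed 4-fold and called 6 of 8972 unchanged genes, and edgeR recovered 31% and 64%. For the 24 h design of 3 against 2, limma recovered 8.25% and 53.1% and called 4 of 8976 unchanged genes, and edgeR recovered 6.19% and 51%. A simulated list of 25 members raised 1.5-fold was called higher in both. These simulated genes varied independently of each other and no unchanged list was simulated, so this does not test the list calls in the real data. Alternatives covered the pseudocount (5), the filter (none, or a mean of at least 20), equal library totals, quantile normalization, voom weights, the replicate letter as a block, fits of only the groups compared, edgeR and leaving out each library in turn. A fit without 2 libraries, called outlying below, and a fit with 1 variance weight per group were chosen after seeing the data. The 2 libraries were bPEI replicate B at 6 h and NoNP replicate B at 24 h. The 24 h controls were only 2, so neither lies farther from their mean. That fit leaves 1 control at 24 h. Chromosome positions were taken from GENCODE release 29 on GRCh38. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.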

Results

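HepG2 cells, an established line from a human hepatocellular carcinoma, were kept in medium alone (NoNP) or exposed to silver nanoparticles at 1.2 ug/mL. The particles carried branched polyethylenimine (bPEI), polyethylene glycol (PEG) or citrate on their surface. Lysates taken at 6, 12 and 24 h were read by TempO-Seq, in which pairs of detector oligonucleotides are ligated on target transcripts, amplified and sequenced. The 32 libraries fell into 12 groups of exposure and time. At 6 h there were 3 NoNP, 3 bPEI, 2 PEG and 2 citrate libraries, at 12 h there were 3 of each, and at 24 h there were 2 NoNP, 2 bPEI, 3 PEG and 3 citrate libraries. Read totals ran from 1313855 (PEG at 6 h, replicate A) to 6735072 (bPEI at 12 h, replicate A), with a median of 3373855. The 24 h controls held 2015520 and 1420319 reads. Between 9111 and 11473 genes had at least 1 read in a library, and 9324 of 13133 genes were tested. Values are normalized reads per gene, each ± is an SD over the libraries of a group, and differences are relative to the group named. For a coating at 1 time, rose and fell mean higher or lower than NoNP at that time, not a change with time. Nothing in the sources used here says that replicates came from separate cultures, so p-values measure only the spread between these samples. Time took 29.2% of the variance and exposure 10.4%, and the 12 groups together took 55.8%. These shares are not adjusted for their 2, 3 and 11 degrees of freedom, so part of each arises by chance. The 24 h controls stood farther apart than the libraries of any other group, with 2.7 times the mean residual variance and a rank correlation across genes of 0.839.

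**Figure D1:**
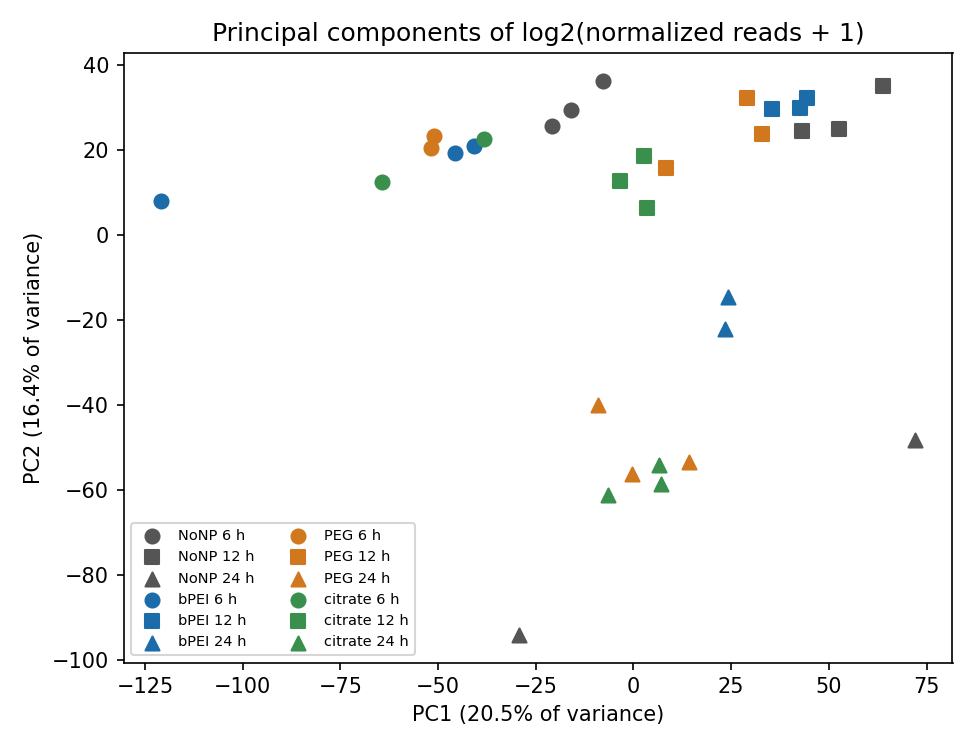
Principal components of the log2 values of the 32 libraries, 1 symbol per library, with the first component (20.5% of the variance) on the horizontal axis and the second (16.4%) on the vertical axis. The 24 h libraries lie lowest on the vertical axis, and 1 bPEI library at 6 h and the 2 NoNP libraries at 24 h lie far from the rest of their groups.

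The untreated cells give the background of the time course, as differences between times without particles. These include any technical difference between the libraries of each time, which was not tested. At 6 h NoNP replicates A and B had 453 and 744 genes with a single read, and replicate C had 182. Genes of cell division were lower at 24 h than at 12 h. Of 25 measured members of a list of G2/M and mitosis genes, 23 fell and 2 were not called (23 adjusted over the list alone, camera adjusted p = 1.23e-18, adjusted p = 0.00119 with an estimated correlation). Of 27 genes of G1/S and DNA replication, 15 fell and 12 were not called (15 over the list alone, camera adjusted p = 2.42e-09, adjusted p = 0.00391 with an estimated correlation). Nitric oxide synthase NOS3 rose from 1.73 ± 0.599 (SD, n = 3) at 12 h to 153 ± 41.8 at 24 h (SD, n = 2; limma adjusted p = 4.6e-09). Cystatin transcripts assigned to CST2 (chromosome 20, 23823769 to 23826731, GRCh38) rose from 26.1 ± 10.4 (n = 3) at 6 h to 2872 ± 337 (n = 2) at 24 h (limma adjusted p = 1.53e-08). GSTA1, a glutathione transferase of hepatocytes, fell from 185 ± 15.8 (n = 3) at 6 h to 0 at 24 h, at least 68.1-fold lower (limma adjusted p = 6.46e-09).

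Earlier in the control course, acute phase proteins fell between 6 and 12 h in 11 of 18 measured members, with 7 not called (over the list alone 1 higher and 14 lower, camera adjusted p = 3.77e-12, adjusted p = 0.00287 with an estimated correlation). Secreted hepatocyte proteins changed in 10 of 23 members, 1 higher and 9 lower, with 13 not called (1 and 10 over the list alone). Their camera adjusted p was 8.15e-05, and the adjusted p = 0.137 with an estimated correlation. The interferon-inducible GTPase GBP1 fell from 455 ± 33.1 (SD, n = 3) to 21.04 ± 8.32 (SD, n = 3; limma adjusted p = 1.02e-11). The zinc finger gene ZNF114 rose from 52.7 ± 8.23 to 1110 ± 214 (limma adjusted p = 4.04e-09). From 6 to 24 h, genes of cholesterol synthesis and uptake fell in 11 of 23 members with 12 not called (12 over the list alone, camera adjusted p = 1.14e-05, adjusted p = 0.00413 with an estimated correlation). The limma fit called 1097 genes from 6 to 12 h (456 higher and 641 lower), 1731 from 6 to 24 h (726 and 1005) and 1708 from 12 to 24 h (754 and 954). Camera called 9 lists in each of these steps, of which 1, 5 and 3 held with an estimated correlation. The count of 1097 fell to 580 and 659 without NoNP replicate B or A at 12 h, and to 648 and 662 without replicate A or C at 6 h. From 12 to 24 h 759 genes passed without NoNP replicate B at 24 h and 2882 without replicate A. With the spread of only the groups compared the 3 counts were 2186, 531 and 152, and with 1 variance weight per group, a fit chosen after seeing the data, 2187, 466 and 266.

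**Figure D2:**
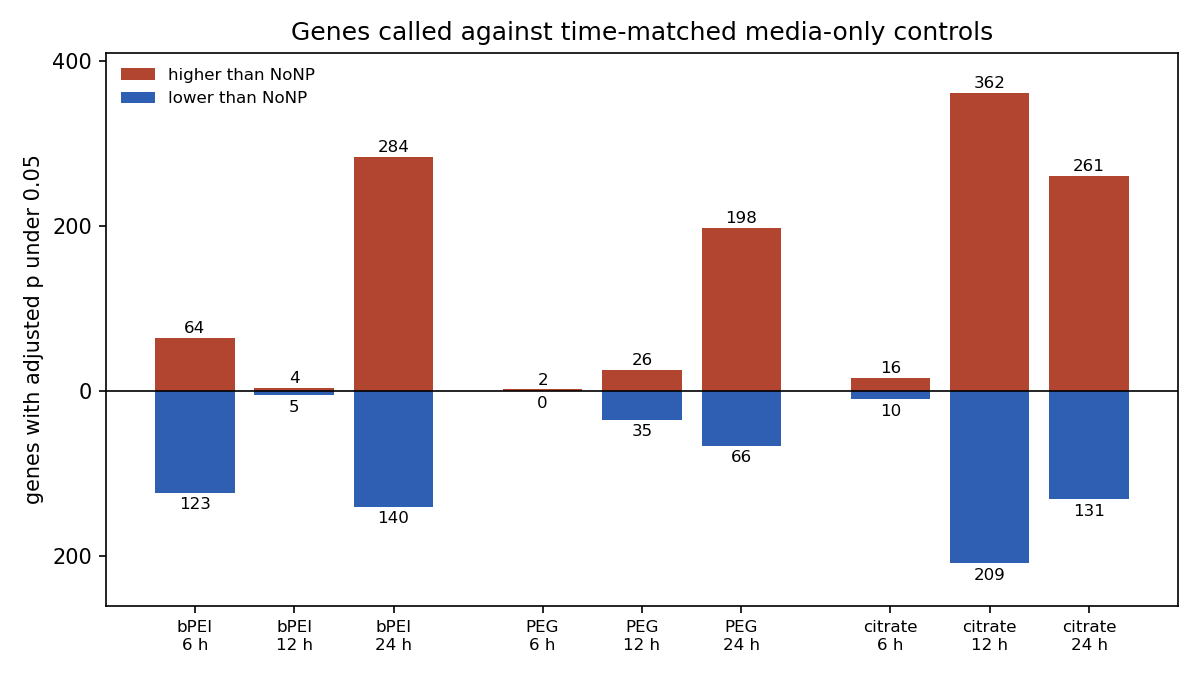
Number of genes with a limma adjusted p under 0.05 against the NoNP libraries of the same time, with genes higher than NoNP above the 0 line and genes lower than NoNP under it. The bars run from 2 genes for PEG at 6 h to 571 for citrate at 12 h (362 higher and 209 lower).

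The comparisons of each coating with the controls of the same time ask what a low dose of silver did to gene levels and whether its surface mattered. With citrate-coated particles at 6 h, the stress-inducible chaperone gene HSPA6 (chromosome 1, 161524540 to 161526910, GRCh38) rose from 3.17 ± 5.02 (SD, n = 3) to 597 ± 158 (SD, n = 2; limma adjusted p = 0.000118). The co-chaperone FKBP4 rose from 28.0 ± 7.66 to 147 ± 42.3 (limma adjusted p = 0.00196). PPP1R15A, which helps end the integrated stress response, rose from 437 ± 145 to 1654 ± 360 (limma adjusted p = 0.00108), and the small MAF factor MAFF from 104 ± 31.4 to 491 ± 142 (limma adjusted p = 0.0033). Collagenase MMP1 was at 0 in the 3 controls and at 69.2 ± 13.7 with citrate, at least 73.8-fold higher (limma adjusted p = 0.0297). The IL-33 receptor IL1RL1 was at least 21.7-fold higher, at 25.7 ± 20.6 (limma adjusted p = 0.0299). Among falls, the sulfotransferase CHST7 went from 25.03 ± 9.38 to 0, at least 15.9-fold lower (limma adjusted p = 0.00157). The actin crosslinker ACTN1 fell from 5552 ± 274 to 3152 ± 15.04 (limma adjusted p = 0.019). Over 16 alternatives, each with 1 setting changed, 1 library left out or both outlying libraries left out, the calls of MMP1, IL1RL1 and ACTN1 held in 8, 7 and 11.

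Immediate early genes, which respond within minutes to growth factors and stress, rose in 2 of 18 measured members at 6 h with citrate, none fell and 16 were not called. Adjusted over the list alone 7 rose, with a camera adjusted p = 9.44e-07 and an adjusted p = 0.0876 with an estimated correlation. The members that passed were MYC, from 814 ± 190 (SD, n = 3) to 1718 ± 129 (SD, n = 2; limma adjusted p = 0.0174), and IER2, from 165 ± 45.2 to 493 ± 28.3 (limma adjusted p = 0.0447). In the heat shock list 1 of 21 members rose, HSPA6, and 20 were not called (3 over the list alone, camera adjusted p = 0.00399, adjusted p = 0.235 with an estimated correlation). HSP90AB1 had 2271 ± 244 against 1128 ± 209 and HSPA1B 312 ± 54.8 against 139 ± 14.9, neither past the threshold. The respiratory chain list was called lower by camera (adjusted p = 0.0268, adjusted p = 0.59 with an estimated correlation) with 0 of 29 members called by limma over all genes and 0 over the list alone. In all, 26 genes were called, 16 higher and 10 lower (edgeR 21). The count was 7 without citrate replicate C, and 8, 9 and 14 without NoNP replicate B, C or A. It was 242 with the spread of only the groups compared, 188 with 1 variance weight per group, and 260 without both outlying libraries (bPEI replicate B at 6 h and NoNP replicate B at 24 h), the last 2 being fits chosen after seeing the data.

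PEG-coated particles at 6 h left 2 genes past the threshold. HSPA6 rose from 3.17 ± 5.02 (SD, n = 3) to 504 ± 437 (SD, n = 2; limma adjusted p = 0.000532), and the canalicular exporter ABCC2 from 684 ± 136 to 1463 ± 3.13 (limma adjusted p = 0.0275). PPP1R15A had 1195 ± 321 with PEG against 437 ± 145 in NoNP (limma adjusted p = 0.0584), PRPSAP2 2.11 ± 0.382 against 28.3 ± 6.14 (limma adjusted p = 0.0555) and TCHP 223 ± 26.1 against 71.9 ± 10.8 (limma adjusted p = 0.0951), none of the 3 past the threshold. Immediate early genes were called higher by camera (adjusted p = 0.00351, adjusted p = 0.286 with an estimated correlation), with 0 of 18 members passing singly and 0 over the list alone. Of these, IER2 had 361 ± 42.7 against 165 ± 45.2. Xenobiotic metabolism was called lower (camera adjusted p = 0.0251, adjusted p = 0.093 with an estimated correlation) with 0 of 13 members passing in either adjustment. CYP1A1 had 179 ± 19.2 against 342 ± 137. The respiratory chain was also called lower (camera adjusted p = 4.13e-05, adjusted p = 0.362 with an estimated correlation) with 0 of 29 members passing in either adjustment. The 2 libraries of PEG differed in HSPA6 (813 and 195 normalized reads), and 0 genes passed in limma without PEG replicate A, 1 without NoNP replicate C and 16 without PEG replicate C. The count was 113 with the spread of only the groups compared, 41 with 1 variance weight per group and 159 without both outlying libraries, and the call of ABCC2 held in 11 of 16 alternatives. By edgeR 2 genes passed, and 787 had an unadjusted p under 0.05 in limma.

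With bPEI-coated particles at 6 h LAMP2, a membrane protein of the lysosome, fell from 787 ± 228 (SD, n = 3) to 75.2 ± 55.5 (SD, n = 3; limma adjusted p = 0.0256). The lysosome and autophagy list had 4 of 25 members lower, none higher and 21 not called (9 lower over the list alone, camera adjusted p = 0.00896, adjusted p = 0.302 with an estimated correlation). The proton pump subunit ATP6V1A fell from 161 ± 26.9 to 55.7 ± 16.0 (limma adjusted p = 0.00987) and the cholesterol transporter NPC1 from 518 ± 64.5 to 261 ± 32.1 (limma adjusted p = 0.0381). Ribosomal protein genes fell in 5 of 50 members with 45 not called (over the list alone 3 higher and 13 lower, camera adjusted p = 0.0173, adjusted p = 0.751 with an estimated correlation). RPS3A fell from 11630 ± 734 to 6926 ± 1322 (limma adjusted p = 0.00733) and RPL30 from 2419 ± 49.5 to 905 ± 440 (limma adjusted p = 0.0281). The nuclear adaptor TRRAP rose from 0.914 ± 1.58 to 27.8 ± 10.2 (limma adjusted p = 0.00564). AGFG2 rose from 66.5 ± 30.97 to 298 ± 112 (limma adjusted p = 0.00564), and POLD2, a subunit of DNA polymerase delta, from 25.9 ± 8.16 to 114 ± 18.6 (limma adjusted p = 0.0256).

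The respiratory chain list had 1 member higher and 1 lower, COX7A2, of 29 with bPEI at 6 h, and 27 not called (1 and 6 over the list alone, camera adjusted p = 0.00317, adjusted p = 0.527 with an estimated correlation). COX7A2, a subunit of cytochrome oxidase, fell from 98.3 ± 37.1 (SD, n = 3) to 33.2 ± 27.6 (SD, n = 3; limma adjusted p = 0.0487). Of the 187 genes called, 64 were higher and 123 lower, and with equal library totals the split was 70 and 68. bPEI replicate B stood apart from the other 2 libraries, and the called genes had a median log2 change in their direction of 1.9 in that library alone and 0.99 without it. The count was 6 without bPEI replicate B, 11, 26 and 34 without NoNP replicate B, C or A, and 553 and 569 without bPEI replicate A or C. With the spread of only the groups compared 1 gene passed, and 108 passed without both outlying libraries. The calls of LAMP2, NPC1 and COX7A2 held in 11, 10 and 7 of 17 alternatives.

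At 12 h the citrate-coated particles gave the most called genes of the 9 comparisons in the fit of all libraries. The comparisons differ in their numbers of libraries, so their counts are not on equal terms. Stromelysin MMP3 (chromosome 11, 102835801 to 102843803, GRCh38) rose from 21.6 ± 7.81 (SD, n = 3) to 590 ± 256 (SD, n = 3; limma adjusted p = 0.000994). MMP1 (chromosome 11, 102789920 to 102798160) rose from 6.58 ± 5.70 to 269 ± 82.8 (limma adjusted p = 0.00298), and MMP10 from 1.93 ± 3.35 to 33.0 ± 20.1 (limma adjusted p = 0.0474). IL1RL1 (chromosome 2, 102311502 to 102352037) was at 0 in the controls and at 49.8 ± 12.4 with citrate, at least 75.3-fold higher (limma adjusted p = 0.000305). HSPA6 was at 0 and 45.5 ± 5.95, at least 71.1-fold higher (limma adjusted p = 0.00055). The zinc transporter SLC39A14 fell from 24.0 ± 7.97 to 1.84 ± 3.19 (limma adjusted p = 0.0335). The desmosomal cadherin DSC2 fell from 34.7 ± 20.9 to 1.30 ± 2.25 (limma adjusted p = 0.0112), and ANKRD50 from 24.0 ± 18.2 to 0, at least 28.4-fold lower (limma adjusted p = 0.00603). The calls of MMP10 and SLC39A14 each held in 10 of 16 alternatives and not in edgeR (adjusted p = 0.0983 and 0.0924, with a range over the alternatives of 0.0127 to 0.2 and 0.00773 to 0.153).

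By list, 7 of 24 members of the list of extracellular matrix, adhesion and YAP or TGF beta targets rose at 12 h with citrate, 1 fell and 16 were not called (8 and 1 over the list alone, camera adjusted p = 0.000605, adjusted p = 0.166 with an estimated correlation). Thrombospondin THBS1 rose from 216 ± 124 (SD, n = 3) to 667 ± 41.7 (SD, n = 3; limma adjusted p = 0.000309). Connective tissue growth factor CTGF rose from 233 ± 103 to 699 ± 193 (limma adjusted p = 0.000994). Immediate early genes rose in 3 of 18 members with 15 not called (5 over the list alone, camera adjusted p = 0.0251, adjusted p = 0.426 with an estimated correlation). MYC rose from 603 ± 68.3 to 1354 ± 176 (limma adjusted p = 0.000534). Xenobiotic metabolism fell in 2 of 13 members with 11 not called (3 over the list alone, camera adjusted p = 0.0207, adjusted p = 0.0901 with an estimated correlation). These were the monooxygenases CYP3A7, from 140 ± 12.3 to 32.9 ± 15.4 (limma adjusted p = 0.00183), and CYP3A5, from 162 ± 10.7 to 51.0 ± 12.7 (limma adjusted p = 0.00524). In the respiratory chain list 1 member rose, 3 fell and 25 were not called (1 and 4 over the list alone, camera adjusted p = 0.00526, adjusted p = 0.534 with an estimated correlation). UQCRC2 of complex III fell from 1516 ± 56.6 to 838 ± 68.5 (limma adjusted p = 0.00518). Among antioxidant enzymes 1 of 19 fell, the glutathione peroxidase GPX2, from 1069 ± 139 to 333 ± 76.3 (limma adjusted p = 0.00728), and 18 were not called (1 over the list alone, camera adjusted p = 0.0237, adjusted p = 0.472 with an estimated correlation). The limma fit called 571 genes, 362 higher and 209 lower, against 485 and 167 with equal library totals. The count fell to 146 without citrate replicate B and to 159 and 234 without NoNP replicate B or A. It rose to 1212 with voom weights, 1262 with the spread of only the groups compared, 1333 with 1 variance weight per group and 1414 without both outlying libraries.

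With PEG at 12 h several of these genes rose too. MMP3 rose from 21.6 ± 7.81 (SD, n = 3) to 522 ± 104 (SD, n = 3; limma adjusted p = 0.00582) and MMP1 from 6.58 ± 5.70 to 133 ± 48.0 (limma adjusted p = 0.0459). IL1RL1 went from 0 to 77.8 ± 33.1, at least 118-fold higher (limma adjusted p = 0.000275), and HSPA6 from 0 to 43.2 ± 10.2, at least 70.4-fold higher (limma adjusted p = 0.00335). The phospholyase ETNPPL (chromosome 4, 108742040 to 108763054) was lower with PEG, at 81.5 ± 14.0 against 492 ± 203 (limma adjusted p = 0.000275). At 6 h ETNPPL had 90.54 and 61.27 in the PEG libraries and 145.7, 99.11 and 92.17 in NoNP. The mitochondrial NAD kinase NADK2 fell from 1295 ± 266 to 439 ± 55.8 (limma adjusted p = 0.00335), and the chromatin reader ING3 from 40.7 ± 4.62 to 0.907 ± 1.57 (limma adjusted p = 0.0107). In the list of extracellular matrix, adhesion and YAP or TGF beta targets, 3 of 24 members rose, none fell and 21 were not called (4 over the list alone, camera adjusted p = 0.0114, adjusted p = 0.295 with an estimated correlation). They were THBS1, to 592 ± 87.7 from 216 ± 124 (limma adjusted p = 0.00347), CTGF, to 601 ± 160 from 233 ± 103 (limma adjusted p = 0.0137), and the keratin KRT8, to 14660 ± 2319 from 8014 ± 2439 (limma adjusted p = 0.041).

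Camera called 3 more lists with PEG at 12 h in which 0 members passed over all genes. Xenobiotic metabolism was lower (3 of 13 members over the list alone, camera adjusted p = 0.00351, adjusted p = 0.0856 with an estimated correlation). CYP3A7 had 49.8 ± 7.42 (SD, n = 3) against 140 ± 12.3 (SD, n = 3). NF-kB and chemokine genes were higher (1 of 16 over the list alone, camera adjusted p = 0.0335, adjusted p = 0.18 with an estimated correlation). The chemokine CXCL2 had 14.3 ± 2.59 against 3.04 ± 2.68. Lysosome and autophagy was lower (0 of 25 over the list alone, camera adjusted p = 0.0449, adjusted p = 0.433 with an estimated correlation). The limma fit called 61 genes, 26 higher and 35 lower, against 46 and 24 with equal library totals. The count was 9 and 24 without NoNP replicate A or B, and 12, 24 and 30 without PEG replicate C, A or B. It was 185 with voom weights, 165 with the spread of only the groups compared, 249 with 1 variance weight per group and 321 without both outlying libraries. The call of MMP1 held in 9 of 17 alternatives.

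With bPEI at 12 h 9 genes passed, 4 higher and 5 lower. POLD2 rose from 3.05 ± 1.71 (SD, n = 3) to 21.4 ± 4.66 (SD, n = 3; limma adjusted p = 0.0339), the growth factor signalling inhibitor SPRY1 from 42.1 ± 8.47 to 119 ± 30.5 (limma adjusted p = 0.0461). CTGF rose from 233 ± 103 to 581 ± 134 (limma adjusted p = 0.0495), and transcripts assigned to the metallothionein MT1G from 195 ± 15.4 to 437 ± 45.7 (limma adjusted p = 0.0461). ETNPPL was lower than in NoNP, at 104 ± 30.4 against 492 ± 203 (limma adjusted p = 0.00747). So was the MO25 family gene CAB39L, at 73.6 ± 14.9 against 277 ± 64.0 (limma adjusted p = 0.0492). The mitochondrial ribosomal protein MRPS6 fell from 1184 ± 299 to 434 ± 87.2 (limma adjusted p = 0.0492), and the translation release factor GSPT1 from 2337 ± 571 to 1154 ± 211 (limma adjusted p = 0.0461). The remaining gene that fell was assigned to KLRC2, from 203 ± 83.3 to 38.86 ± 12.98 (limma adjusted p = 0.0339).

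Of the lists called with bPEI at 12 h, extracellular matrix, adhesion and YAP or TGF beta targets had 1 of 24 members higher, CTGF, and 23 not called (over the list alone 2 higher and 1 lower, camera adjusted p = 0.0488, adjusted p = 0.426 with an estimated correlation). In the other lists no member passed over all genes. NRF2 targets were lower (0 of 29 members higher and 1 lower over the list alone, camera adjusted p = 0.0494, adjusted p = 0.513 with an estimated correlation). AKR1C2 was at 175 ± 5.84 (SD, n = 3) against 512 ± 157 (SD, n = 3). NF-kB and chemokine genes were higher (0 of 16 over the list alone, camera adjusted p = 0.0447, adjusted p = 0.212 with an estimated correlation). So were ribosomal proteins (0 of 50 over the list alone, camera adjusted p = 0.0251, adjusted p = 0.762 with an estimated correlation). By edgeR 16 genes passed, with voom weights 44, with the spread of only the groups compared 138, with 1 variance weight per group 157 and without both outlying libraries 37. Calls of POLD2, CTGF, CAB39L and MRPS6 held in 11, 11, 8 and 10 of 17 alternatives. The limma count was 0 without NoNP replicate A, without bPEI replicate B and without bPEI replicate C, and 1 without NoNP replicate B. With all libraries 446 of 9324 genes had an unadjusted p under 0.05, no more than the share of 0.05 that chance gives.

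**Figure D3:**
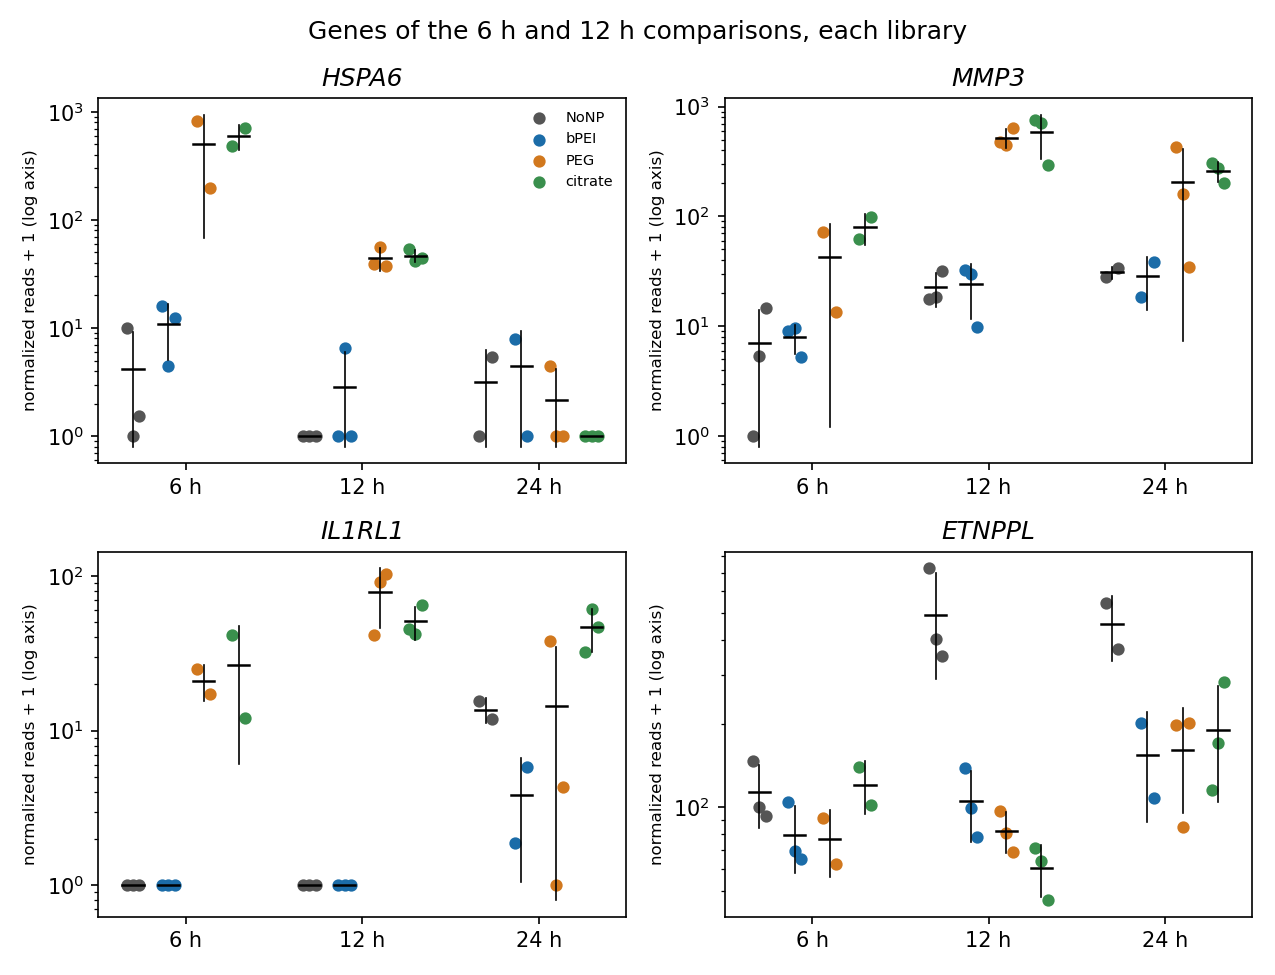
Normalized reads plus 1 on a log axis for HSPA6, MMP3, IL1RL1 and ETNPPL, with 1 point per library, a horizontal line at the mean and a bar of 1 SD either way that ends at the lower edge where the mean less the SD is under 0. At 12 h IL1RL1 was at 0 in all NoNP and bPEI libraries, against means of 77.8 with PEG and 49.8 with citrate.

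At 24 h the comparisons asked what remained a day after exposure, against controls in which fibrinogen and cell division genes had fallen since 6 or 12 h. With bPEI at 24 h fibrinogen gamma FGG (chromosome 4, 154604134 to 154612967) stood at 5640 ± 121 (SD, n = 2) against 929 ± 24.6 (SD, n = 2; limma adjusted p = 5.41e-11). In the same comparison fibrinogen beta FGB was at 1611 ± 252 against 257 ± 58.8 (limma adjusted p = 8.85e-10) and haptoglobin HP at 735 ± 40.3 against 166 ± 6.46 (limma adjusted p = 2.86e-08). The antimicrobial peptide gene LEAP2 stood at 219 ± 17.95 against 5.95 ± 3.88 (limma adjusted p = 2.6e-09). The gluconeogenic phosphatase G6PC had 84.8 ± 21.9 against 3.26 ± 4.61, and its 3 control reads gave a ratio of 31.2 with a 95% counting interval of 10.6 to 153 (limma adjusted p = 2.74e-05). The chemokine CXCL1 stood at 34.8 ± 3.51 against 0, at least 12.4-fold higher (limma adjusted p = 0.000643). CST2 was lower with bPEI, at 60.3 ± 21.2 against 2872 ± 337 (limma adjusted p = 2.74e-05). So were CST1, at 2.24 ± 0.717 against 313 ± 74.6 (limma adjusted p = 0.000547), and the collagen VI chain COL6A1, at 1.37 ± 1.94 against 53.6 ± 34.9 (limma adjusted p = 0.000208).

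By list, bPEI at 24 h was higher than NoNP in 11 of 25 G2/M and mitosis genes with 14 not called (17 over the list alone, camera adjusted p = 4.92e-11, adjusted p = 0.0856 with an estimated correlation). The hyaluronan-mediated motility receptor HMMR had 288 ± 44.5 (SD, n = 2) against 54.3 ± 15.5 (SD, n = 2; limma adjusted p = 0.000113). G1/S and DNA replication genes were higher in 7 of 27 with 20 not called (10 over the list alone, camera adjusted p = 6.48e-06, adjusted p = 0.0856 with an estimated correlation). The replication factor GINS2 had 68.5 ± 18.2 against 3.78 ± 0.807 (limma adjusted p = 4.75e-08). DNA repair was higher in 3 of 21 with 18 not called (over the list alone 7 higher and 1 lower, camera adjusted p = 0.0341, adjusted p = 0.223 with an estimated correlation). Acute phase proteins were higher in 5 of 18 with 13 not called (7 higher and 1 lower over the list alone, camera adjusted p = 4.21e-06, adjusted p = 0.0901 with an estimated correlation). Cholesterol synthesis and uptake was higher in 4 of 23 with 19 not called (6 over the list alone, camera adjusted p = 0.000545, adjusted p = 0.0856 with an estimated correlation). ATF4 targets were lower in 5 of 24 with 19 not called (7 over the list alone, camera adjusted p = 7.36e-08, adjusted p = 0.0901 with an estimated correlation). The stress cytokine GDF15 (chromosome 19, 18374731 to 18389176) had 5150 ± 2048 against 22610 ± 435 (limma adjusted p = 2.74e-05).

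NRF2 targets were lower with bPEI at 24 h in 2 of 29 members with 27 not called (2 over the list alone, camera adjusted p = 0.0251, adjusted p = 0.426 with an estimated correlation). Sulfiredoxin SRXN1 had 75.4 ± 3.64 (SD, n = 2) against 353 ± 109 (SD, n = 2; limma adjusted p = 0.00257). Immediate early genes were lower in 1 of 18 with 17 not called (2 over the list alone, camera adjusted p = 0.0203, adjusted p = 0.417 with an estimated correlation), the ERK phosphatase DUSP6, at 105 ± 5.29 against 375 ± 190 (limma adjusted p = 0.0147). The limma fit called 424 genes, 284 higher and 140 lower, against 348 and 98 with equal library totals. The count was 90 and 221 without bPEI replicate B or A, and 1632 without NoNP replicate A. The call of DUSP6 held in 9 of 15 alternatives. With the spread taken from only the 2 groups compared, 1 gene passed in limma, while 1694 had an unadjusted p under 0.05 in the fit of all libraries.

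PEG at 24 h gave higher levels of the same fibrinogen and haptoglobin genes. HP had 477 ± 90.2 (SD, n = 3) against 166 ± 6.46 (SD, n = 2; limma adjusted p = 1.1e-05). FGB had 700 ± 65.0 against 257 ± 58.8 (limma adjusted p = 4.15e-05) and FGG 2241 ± 534 against 929 ± 24.6 (limma adjusted p = 4.33e-05). Acute phase proteins were higher in 5 of 18 with 13 not called (5 higher and 1 lower over the list alone, camera adjusted p = 0.00399, adjusted p = 0.286 with an estimated correlation). G2/M and mitosis genes were higher in 6 of 25 with 19 not called (10 over the list alone, camera adjusted p = 1.97e-06, adjusted p = 0.093 with an estimated correlation). HMMR was at 160 ± 64.1 against 54.3 ± 15.5 (limma adjusted p = 0.0115). G1/S and DNA replication genes were higher in 3 of 27 with 24 not called (7 over the list alone, camera adjusted p = 8.85e-05, adjusted p = 0.0901 with an estimated correlation). GINS2 was at 47.0 ± 12.6 against 3.78 ± 0.807 (limma adjusted p = 7.03e-07). ATF4 targets were lower in 3 of 24 with 21 not called (3 over the list alone, camera adjusted p = 3.17e-05, adjusted p = 0.191 with an estimated correlation). GDF15 was at 7631 ± 3745 against 22610 ± 435 (limma adjusted p = 0.000706).

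Single genes named for PEG at 24 h included G6PC, at 65.6 ± 21.6 (SD, n = 3) against 3.26 ± 4.61 (SD, n = 2), with a ratio of 25.8 and a 95% counting interval of 8.73 to 126 (limma adjusted p = 4.15e-05). CXCL1 had 24.7 ± 11.4 against 0, at least 9.13-fold higher (limma adjusted p = 0.00166). MRPS6 was lower than in NoNP, at 1046 ± 172 against 4076 ± 861 (limma adjusted p = 0.000882). Also lower were CST2, at 522 ± 91.5 against 2872 ± 337 (limma adjusted p = 0.0496), and the ubiquitin-conjugating enzyme CDC34, at 10.6 ± 9.86 against 77.7 ± 10.1 (limma adjusted p = 0.0183). Within the PEG groups CST2 was higher at 24 h than at 12 h, where the libraries had 35.05, 8.158 and 10.59. Of 264 genes called, 198 were higher and 66 lower, against 308 and 48 with equal library totals. The count was 116 and 139 without PEG replicate B or C, 620 and 816 without NoNP replicate B or A, and 1084 without both outlying libraries. Of the calls named for PEG, those of CST2 and HMMR held in 6 and 10 of 16 alternatives. In limma 0 genes passed with the spread of only the 2 groups compared, edgeR called 145, and 1550 genes had an unadjusted p under 0.05 in the fit of all libraries.

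With citrate at 24 h HP had 515 ± 30.7 (SD, n = 3) against 166 ± 6.46 (SD, n = 2; limma adjusted p = 2.3e-06) and FGG 2258 ± 294 against 929 ± 24.6 (limma adjusted p = 2.92e-05). Acute phase proteins were higher in 5 of 18, lower in 1 and not called in 12 (5 and 1 over the list alone, camera adjusted p = 0.0335, adjusted p = 0.426 with an estimated correlation). G2/M and mitosis genes were higher in 8 of 25 with 17 not called (16 over the list alone, camera adjusted p = 3.77e-08, adjusted p = 0.0856 with an estimated correlation). The mitotic kinase NEK2 had 151 ± 9.98 against 42.7 ± 23.5 (limma adjusted p = 0.000447). G1/S and DNA replication genes were higher in 5 of 27 with 22 not called (9 over the list alone, camera adjusted p = 6.42e-05, adjusted p = 0.0901 with an estimated correlation). GINS2 was at 51.6 ± 22.6 against 3.78 ± 0.807 (limma adjusted p = 2.44e-07). DNA repair was higher in 2 of 21 with 19 not called (6 over the list alone, camera adjusted p = 0.036, adjusted p = 0.228 with an estimated correlation). ATF4 targets were lower in 5 of 24 with 19 not called (7 over the list alone, camera adjusted p = 2.13e-07, adjusted p = 0.0901 with an estimated correlation). GDF15 was at 5291 ± 191 against 22610 ± 435 (limma adjusted p = 2.25e-05), and the folate enzyme MTHFD2 at 327 ± 34.4 against 913 ± 57.2 (limma adjusted p = 0.000149).

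NRF2 targets were lower with citrate at 24 h, with 1 of 29 members higher, 2 lower and 26 not called (1 and 3 over the list alone, camera adjusted p = 0.0172, adjusted p = 0.417 with an estimated correlation). Ferritin heavy chain FTH1 had 2302 ± 216 (SD, n = 3) against 3708 ± 157 (SD, n = 2; limma adjusted p = 0.0198). The lysosome and autophagy list was lower in 3 of 25 with 22 not called (4 over the list alone, camera adjusted p = 0.0349, adjusted p = 0.426 with an estimated correlation). Cathepsin CTSB had 7307 ± 64.9 against 16460 ± 5379 (limma adjusted p = 0.00164). The proteasome activator PSME2 had 28.2 ± 7.19 against 0, at least 9.89-fold higher (limma adjusted p = 0.0003). G6PC had 78.3 ± 51.1 against 3.26 ± 4.61, a ratio of 27.9 with a 95% counting interval of 9.36 to 137 (limma adjusted p = 3.9e-05). The limma fit called 392 genes, 261 higher and 131 lower, against 423 and 89 with equal library totals. The count was 223 and 261 without citrate replicate A or B, 819 and 852 without NoNP replicate A or B, and 1229 without both outlying libraries. With the spread of only the 2 groups compared 1 gene passed, and edgeR called 202. The call of FTH1 held in 9 of 16 alternatives.

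**Figure D4:**
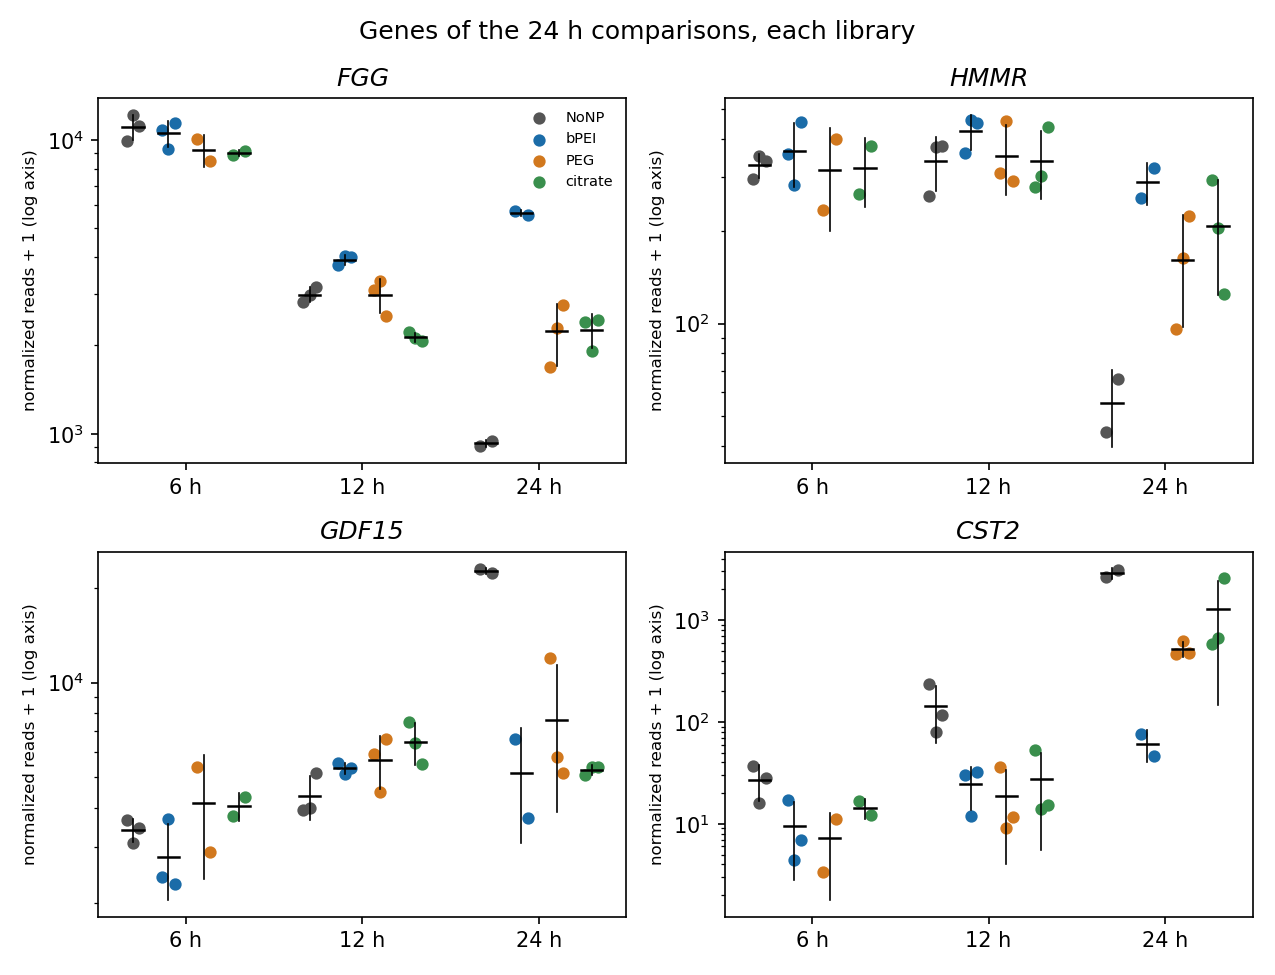
Normalized reads plus 1 on a log axis for FGG, HMMR, GDF15 and CST2, with 1 point per library, a horizontal line at the mean and a bar of 1 SD either way. At 24 h FGG was at 929 in NoNP against 5640 with bPEI, 2241 with PEG and 2258 with citrate, after 11100 in NoNP at 6 h.

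For scaling, equal library totals moved the median log2 difference of all genes at 24 h to 0.2 (bPEI), 0.182 (PEG) and 0.206 (citrate), from 0.0981, 0.0479 and 0.0437 with the deposited factors. Among all tested genes, the libraries of a coating and of NoNP did not overlap in 24.8%, 19.1% and 36.4% for bPEI at 6, 12 and 24 h, where chance gives 10%, 10% and 33.3%. For PEG the shares were 32.1%, 20.8% and 21.9% against 20%, 10% and 20%, and for citrate 34.9%, 32.3% and 23.2% against 20%, 10% and 20%. Of 261 list tests 41 were called by camera with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.0856, while fry called 37 and kept 24 of the 41. At 24 h 43, 9 and 7 genes passed for bPEI, PEG and citrate with 1 variance weight per group, a fit chosen after seeing the data. In each of the 41 list calls, the median, the mean and the test had the same sign.

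Whether the coatings had genes in common was asked of the 3 sets of calls at each time. At 12 h POLD2, CTGF and SPRY1 were higher and ETNPPL, CAB39L, MRPS6 and GSPT1 lower with every coating, 7 of the 582 genes called in any, and these were named after their calls were seen. With bPEI 0 genes passed in limma at 12 h without NoNP replicate A, bPEI replicate B or bPEI replicate C. No gene was then shared by all 3. With all libraries edgeR called 16 for bPEI, and 446 of 9324 genes had an unadjusted p under 0.05 in limma, no more than chance gives. At 24 h 142 of 666 were called alike in all 3, 108 higher and 34 lower, and at 6 h 0 of 204. With the spread of only the groups compared no gene passed in limma with PEG at 24 h, so none was then shared by all 3. In the fit of all libraries 1550 genes had an unadjusted p under 0.05 for that comparison. The pairs bPEI and PEG, bPEI and citrate, and PEG and citrate shared 7, 7 and 52 calls at 12 h. PEG and citrate shared 26 higher and 26 lower, where independent sets give 1.01 and 0.785. At 24 h the pairs shared 132, 140 and 148 higher genes, where independent sets give 6.03, 7.95 and 5.54, and 39, 53 and 44 lower genes, where they give 0.991, 1.97 and 0.927. All coatings were set against the same control libraries, which by itself makes fold changes correlate. Across genes, which are not independent replicates, the correlation of log2 fold changes was 0.62, 0.59 and 0.58 at 6 h, 0.58, 0.46 and 0.69 at 12 h and 0.73, 0.69 and 0.77 at 24 h. Simulated unchanged groups against shared controls gave 0.35 for each pair at 6 h, 0.52, 0.51 and 0.44 at 12 h and 0.78, 0.76 and 0.77 at 24 h. The covariance exceeded the simulated mean by 0.266, 0.252 and 0.216 at 6 h and by 0.1, 0.0949 and 0.293 at 12 h, and differed from it by -0.00541, -0.0343 and -0.0331 at 24 h. The simulations shared at most 0 calls at 6 and 12 h and at most 30, 33 and 71 at 24 h. Simulated genes varied independently of each other and were fitted without the intensity trend and robust moderation. These simulated counts therefore do not bound what chance gives. With 2 or 3 control libraries per time the controls were too few to split, and part of the excess may come from the shared controls.

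Differences among the coatings ask whether gene levels differed between the coated particles at an equal dose. No group received a coating without silver, so a difference cannot be assigned to surface chemistry alone. At 6 h the F test over the 3 coatings called 10 genes, led by PPP1R15A, HSPA6 and ID1 (limma adjusted p = 0.00467 each). PPP1R15A had 453 ± 63.7 (SD, n = 3) with bPEI, 1195 ± 321 (SD, n = 2) with PEG and 1654 ± 360 (SD, n = 2) with citrate. ID1, an inhibitor of differentiation, had 2344 ± 317, 4763 ± 630 and 6143 ± 62.5, and the growth factor HBEGF 135 ± 12.1, 309 ± 126 and 398 ± 76.7. The gluconeogenic enzyme PCK1 had 26.7 ± 8.35, 316 ± 99.6 and 256 ± 82.0 (limma adjusted p = 0.0183). Between pairs of coatings, 7 genes were higher with citrate than with bPEI, among them HSPA6, at 597 ± 158 against 9.88 ± 5.85, with a log2 difference of 5.95 ± 1.05 (SE; limma adjusted p = 0.00616). By limma 0 genes differed between PEG and bPEI, where 542 had an unadjusted p under 0.05 and edgeR called 3, and 0 between citrate and PEG, where 281 had an unadjusted p under 0.05 and edgeR called 0. Of 9324 tested genes chance gives a share of 0.05 at that p, which 281 did not reach and 542 exceeded. The 7 genes of citrate against bPEI became 4 without bPEI replicate B or citrate replicate C and 13 without bPEI replicate C, and the 0 of PEG against bPEI became 11 without PEG replicate C. For HSPA6 the log2 difference of citrate from PEG was 0.56 ± 1.15 (SE). The F test count was 1 without bPEI replicate B, 5 without PEG replicate A and 23 without PEG replicate C. It was 1 with the spread of only the groups compared, 4 with 1 variance weight per group and 25 without both outlying libraries.

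At 12 h the F test called 39 genes. IL1RL1 (limma adjusted p = 0.000242) was at 0 in the bPEI libraries, as in NoNP, and MMP3 (limma adjusted p = 0.00645) at 23.1 ± 12.5 (SD, n = 3) with bPEI against 522 ± 104 (SD, n = 3) with PEG and 590 ± 256 (SD, n = 3) with citrate. These were the 2 genes called between PEG and bPEI, and the log2 difference of MMP3 was 4.60 ± 0.79 (SE). The 2 became 1 without bPEI replicate A or C or any 1 PEG library, 11 with the spread of only the groups compared and 15 with 1 variance weight per group. The call of MMP3 held in 12 of 17 alternatives and that of IL1RL1 in all 17. Albumin ALB (limma adjusted p = 0.0108) had 231400 ± 11200 with bPEI, 157200 ± 15760 with PEG and 122200 ± 5734 with citrate, and complement factor CFB (limma adjusted p = 0.00958) 1035 ± 67.5, 716 ± 130 and 504 ± 14.3. The ETS factor ELK3 (limma adjusted p = 0.00604) had 207 ± 25.8, 397 ± 31.2 and 714 ± 67.4. Citrate differed from bPEI in 130 genes, 87 higher and 43 lower, and from PEG in 2, GNAZ, at 228 ± 25.8 against 84.2 ± 1.62, and JAK3, at 22.7 ± 8.84 against 1.18 ± 2.04. The 130 genes became 11, 17 and 38 without bPEI replicate B, A or C, and 17, 49 and 80 without citrate replicate B, C or A. They became 253 by edgeR, 235 with the replicate block, 220 with equal library totals, 749 with voom weights, 1023 without both outlying libraries, 1400 with 1 variance weight per group and 1471 with the spread of only the groups compared. No gene passed between citrate and PEG without PEG replicate A or B or any 1 citrate library, and 8 passed without PEG replicate C. GNAZ and JAK3 were named after their values were seen (limma adjusted p = 0.0276 each), and their calls held in 10 and 8 of 17 alternatives. The F test count was 2, 7 and 21 without citrate replicate B, C or A, 9, 10 and 21 without bPEI replicate B, A or C, and 25 and 60 without PEG replicate A or C. It was 83 by edgeR, 282 with voom weights, 588 with the spread of only the groups compared, 620 without both outlying libraries and 982 with 1 variance weight per group.

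At 24 h the F test called 14 genes. FGG (limma adjusted p = 4.21e-05) had 5640 ± 121 (SD, n = 2) with bPEI against 2241 ± 534 (SD, n = 3) with PEG and 2258 ± 294 (SD, n = 3) with citrate, and FGB (limma adjusted p = 0.00129) 1611 ± 252, 700 ± 65.0 and 651 ± 96.0. GRB10, an adaptor of the insulin receptor (limma adjusted p = 0.00129), had 56.3 ± 4.89, 245 ± 88.8 and 335 ± 57.6, and TMEM97 (limma adjusted p = 0.00243) 362 ± 47.7, 210 ± 31.5 and 145 ± 26.5. CST2 (limma adjusted p = 0.0117) had 60.3 ± 21.2, 522 ± 91.5 and 1274 ± 1128. PEG differed from bPEI in 5 genes, citrate from bPEI in 17 (8 higher and 9 lower) and citrate from PEG in 1, RNF219, which was at 0 with citrate and at 11.49 ± 5.16 with PEG (limma adjusted p = 0.024). These comparisons use no controls. The 17 genes became 7 and 9 without bPEI replicate B or A and 10 without citrate replicate A. The 5 became 1 without PEG replicate A or B, 2 without bPEI replicate A or B and 13 without PEG replicate C. The 1 became 0 without PEG replicate A or B, 4 without citrate replicate C and 9 without citrate replicate B, and the call of RNF219 held in 6 of 16 alternatives and not in edgeR. The F test count was 4 and 9 without bPEI replicate A or B and 23 without citrate replicate B. It was 46 with the spread of only the groups compared, 40 with 1 variance weight per group and 108 without both outlying libraries.

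The average over the 3 times gives 1 difference per coating. THBS1 was higher with each coating, by a log2 difference of 1.13 (bPEI), 1.35 (PEG) and 1.42 (citrate), and so was the decarboxylase DDC, by 1.80, 1.51 and 1.58. Their limma adjusted p values were 0.000143, 4.9e-05 and 8.3e-06 for THBS1 and 1e-06, 5.39e-05 and 1.95e-05 for DDC. THBS1 and DDC were named after their values were seen, and the difference of DDC depended on time (limma adjusted p = 0.00172 for the interaction). Camera called 9, 9 and 7 of 29 lists for the averages of bPEI, PEG and citrate, and 0 of these held with an estimated correlation, while fry called 11, 8 and 11. Among the called lists, of NF-kB and chemokine genes 2 of 16 were higher with PEG and 14 not called (3 over the list alone, camera adjusted p = 0.00803, adjusted p = 0.0941 with an estimated correlation), with the same counts for citrate (camera adjusted p = 0.0267, adjusted p = 0.111 with an estimated correlation). Lysosome and autophagy genes were lower in 6 of 25 with citrate and 19 not called (7 over the list alone, camera adjusted p = 0.00972, adjusted p = 0.201 with an estimated correlation). Limma called 228 genes for bPEI (127 higher and 101 lower), 367 for PEG (186 and 181) and 1063 for citrate (608 and 455). With equal library totals the splits were 170 and 80, 394 and 115, and 918 and 281. For bPEI the count was 113 and 140 without bPEI replicate B or A at 24 h, 150 without NoNP replicate A at 12 h, and 454 and 611 without NoNP replicate A or B at 24 h. For PEG it was 201 without PEG replicate C at 6 h and 1348 without NoNP replicate B at 24 h, and for citrate 465 without citrate replicate C at 6 h and 656 and 2153 without NoNP replicate A or B at 24 h. The 3 counts were 77, 118 and 446 with 1 variance weight per group and 609, 1896 and 2686 without both outlying libraries.

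The interaction of exposure and time asks whether the difference from the controls depended on time, and it called 62 genes. FGG led (limma adjusted p = 2.04e-06), with 10540 ± 1095 (SD, n = 3) with bPEI against 11100 ± 1113 (SD, n = 3) in NoNP at 6 h, 3917 ± 150 (SD, n = 3) against 2975 ± 175 (SD, n = 3) at 12 h and 5640 ± 121 (SD, n = 2) against 929 ± 24.6 (SD, n = 2) at 24 h. FGB, LEAP2, HP, GINS2 and G6PC were among the 10 with the smallest p, and each had its lowest NoNP mean at 24 h. GDF15 went from 3403 ± 287 at 6 h to 22610 ± 435 at 24 h in NoNP and from 2800 ± 766 to 5150 ± 2048 with bPEI. The bile acid conjugating enzyme BAAT went from 250 ± 57.7 to 32.3 ± 17.9 in NoNP and from 179 ± 17.9 to 256 ± 79.0 with bPEI. The count was 952 and 94 without NoNP replicate A or B at 24 h, 96 without bPEI replicate B at 6 h, 37 and 40 without NoNP replicate C or B at 6 h, 41 without NoNP replicate A at 12 h, 39 and 40 without bPEI replicate B at 12 and 24 h, and 41 without citrate replicate B at 12 h. It was 38 with voom weights, 14 with 1 variance weight per group and 176 without both outlying libraries.

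In the 111 pairs of a gene and a comparison named by the rule, from a list or among the shared calls for a coating against NoNP at 1 time, every treated library lay beyond every control library, which the rule for single genes required. Levels given only for the interaction could overlap, as those of FGG and GDF15 did with bPEI at 6 h. Probe sequences were not used here, so reads of close relatives are not separable and the assignment to CST1, CST2, CST4, MT1G, KLRC2 and HSPA6 is uncertain. The same holds for every other named member of a gene family. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.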

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

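The tests of 1 outlying control library, of low values in the 12 h controls, of collagen-producing cells and of 1 deviating bPEI library were chosen only after the result was seen.

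The results here met the rule that an effect differed between groups by a test of the difference itself. The difference from NoNP depended on time in 62 genes. Among the 10 with the smallest limma adjusted p were FGG (2.04e-06), FGB (1.79e-05), LEAP2 (3.62e-05), HP (4.97e-05), GINS2 (0.000262), G6PC (0.000532), BAAT (0.00077), GDF15 (0.00107) and DDC (0.00172). The test of dependence on time uses the 24 h controls, 2 libraries with 2.7 times the mean residual variance. It called 14 genes with 1 variance weight per group, a fit chosen after seeing the data. The coatings differed among themselves in 10 genes at 6 h, 39 at 12 h and 14 at 24 h.

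At 24 h the 3 coatings shared list calls of higher cell division and acute phase genes and lower ATF4 targets against NoNP, none of which held with an estimated correlation (adjusted p from 0.0856 to 0.426). For the G2/M and mitosis genes alone the tables argue against 1 outlying control library. There the lowest of 6 medians (3 coatings, each against either control) was 0.88 (log2). Of the 142 genes called alike in all coatings, 62% had a mean of at least 100 normalized reads over all libraries. The share among all tested genes was 39.2%. The 62% met the bound set against low depth of the controls. It cannot decide the question, since the mean was not taken over the controls and 85.7% of the 7 genes shared at 12 h also had such a mean. For 1 outlying control the lowest median, in the direction of the list, was 0.46 for G1/S and DNA replication genes and 0.42 for ATF4 targets, between the bounds set, and 0.17 for acute phase proteins, which goes with that explanation. Chance values common to the 2 controls stay open, as the mean covariance of the fold changes, 0.775, lay near the simulated mean of 0.799 and under the highest simulated value of 0.845. Calls shared by pairs of coatings (171, 193 and 192) exceeded the simulated highest of 30, 33 and 71. Simulated genes varied independently of each other and were fitted without the intensity trend and robust moderation. This excess therefore cannot count against chance. A slower change with time in the exposed cells, with medians of the G2/M and mitosis members from 12 to 24 h of -2.52 in NoNP and of -1.36, -1.91 and -1.47 with bPEI, PEG and citrate, may be a biological explanation and remains untested, as does a difference in culture between the 2 control libraries and the rest.

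MMP1, MMP3, IL1RL1 and HSPA6 were called higher with PEG and citrate at 12 h, and MMP10 with citrate only, in limma but not in edgeR (with PEG 30.9 against 1.93 normalized reads, limma adjusted p = 0.147). Low values in the controls alone are argued against by bPEI, from which the lower of the 2 medians of the 5 genes lay 4.54 (log2) away. Collagen-producing cells, a source of matrix metalloproteinases, are argued against by the summed means of COL1A1, COL1A2 and COL3A1. The higher sum was 3.98 normalized reads, where MMP3 had 522 and 590. The collagens were picked from 11 measured markers of other cells, some of which were not low. At 12 h PDGFRB was at 306 with PEG and 329 with citrate, against 330 in NoNP and 343 with bPEI. LYZ was at 3710 and 2630, against 5280 and 5060. Cells that do not make these collagens were not tested. Reads shared with close relatives of HSPA6 were not tested. An effect of the coating may be a biological explanation and stays a hypothesis, since it was found and tested on the same libraries.

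The 187 genes called with bPEI at 6 h rested in part on replicate B. Without it, the median fold change of these genes in the direction called was 0.742 of its value with it (0.99 against 1.33, log2), which lies between the bounds set for and against this explanation. A deviating library and an effect of bPEI cannot be told apart for these genes, since the 3 libraries are too few, and 6 genes passed without replicate B.

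Other splits of the same libraries were counted, the real split included. For 3 libraries against 3 the 10 splits are too few for a share under 0.05. As many genes were called in 1 split for bPEI at 6 h (187, highest other 2), bPEI at 12 h (9, highest other 0), PEG at 12 h (61, highest other 0), citrate at 12 h (571, highest other 0), NoNP from 6 to 12 h (1097, highest other 0), PEG minus bPEI at 12 h (2, highest other 0) and citrate minus bPEI at 12 h (130, highest other 0). As many were called in 2 splits for citrate minus PEG at 12 h (2, highest other 2) and in 5 splits for citrate minus PEG at 24 h (1, highest other 3).

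With 100 splits drawn within times, only the real split called as many genes for the averages of PEG (367, highest other 115) and citrate (1063, highest other 57). The same held for the difference among coatings at 12 h (39, highest other 15). This argues against a random assignment of these libraries to groups. It cannot exclude chance differences between cultures or plates, since replicates may not be separate cultures. For the average of bPEI 2 splits gave as many, a share under 0.05, but the other of these called 468 genes against 228, and what sets that split apart was not tested.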

How the results depend on the processing

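The fits without both outlying libraries and with group variance weights, and 2 of the list tests (without both libraries, and quantile normalization), were tests chosen only after the result was seen. All values are counts of genes called unless named otherwise, comparisons are with NoNP, and the values for 6, 12 and 24 h come in that order. Of the 19 counts of comparisons with NoNP, over time, among the 3 coatings and of the interaction, each is given where it moved by over 1.5 times, and the cause was not tested.

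With a pseudocount of 5, each of the 19 counts stayed within 1.5 times its value. No filter gave 6 for PEG at 6 h and 16 and 25 for the difference among coatings at 6 and 24 h. A minimum mean of 20 gave 9 for that difference at 24 h. Equal library totals gave 67 for it at 12 h. Quantile normalization gave 142 for PEG and 240 for citrate at 24 h. edgeR gave 16 for bPEI at 12 h, 145 for PEG and 202 for citrate at 24 h, and 83 for the difference among coatings at 12 h. With voom weights bPEI gave 112, 44 and 163, PEG 6, 185 and 79, citrate 1212 at 12 h and 76 at 24 h. Voom also gave 282 for the difference among coatings at 12 h, 38 for the interaction and 1659 for NoNP from 6 to 12 h.

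With the spread of only the groups compared, bPEI gave 1, 138 and 1, PEG 113, 165 and 0 (where limma had 1550 at an unadjusted p under 0.05 with all libraries and edgeR 145), and citrate 242, 1262 and 1. The difference among coatings gave 1, 588 and 46. NoNP gave 2186 from 6 to 12 h, 531 from 6 to 24 h and 152 from 12 to 24 h. Group variance weights gave 157 for bPEI at 12 h and 43 at 24 h, 41, 249 and 9 for PEG, and 188, 1333 and 7 for citrate. They gave 77, 118 and 446 for the averages of bPEI, PEG and citrate, 4, 982 and 40 for the difference among coatings, 14 for the interaction, and 2187, 466 and 266 for NoNP from 6 to 12, 6 to 24 and 12 to 24 h. Without both outlying libraries bPEI gave 108 and 37 at 6 and 12 h, PEG 159, 321 and 1084, citrate 260, 1414 and 1229, and the averages 609, 1896 and 2686. The difference among coatings then gave 25, 620 and 108, the interaction 176, and NoNP 1849 from 6 to 12 h and 967 from 12 to 24 h.

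The replicate letter as a block gave 354 and 16 for bPEI at 6 and 12 h, 5 and 94 for PEG at 6 and 12 h, and 6 and 22 for the difference among coatings at 6 and 24 h. NoNP gave 541 from 6 to 12 h and 1012 from 12 to 24 h under the block. The other 11 counts stayed within 1.5 times. The deviations of libraries with the same letter correlated above 0.1 in 2 of 13 pairs at 6 h, 4 of 18 at 12 h and 0 of 13 at 24 h, so the letters were not taken to pair the libraries. At 6 h each library of replicate A or B had more genes with a single read than replicate C of its group, so there the letter marks a shared feature of the libraries. The block has its own terms for the letters within each time, and whether it removes this feature was not tested.

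Leaving out 1 library at a time gave 6 to 569, 0 to 13 and 90 to 1632 for bPEI, 0 to 16, 9 to 71 and 116 to 816 for PEG, and 7 to 34, 146 to 451 and 223 to 852 for citrate. The averages ran from 113 to 611 (bPEI), 201 to 1348 (PEG) and 465 to 2153 (citrate). The difference among coatings ran from 1 to 23, 2 to 60 and 4 to 23, and the interaction from 37 to 952. NoNP ran from 580 to 926 (6 to 12 h), 1370 to 2159 (6 to 24 h) and 759 to 2882 (12 to 24 h). A group left with 1 library was assumed to vary like the other groups. Where the count was 0, for bPEI and PEG, limma had 446 genes at 12 h and 787 at 6 h at an unadjusted p under 0.05 with all libraries, and edgeR had 16 and 2. The 446 lay under the share of 0.05 of 9324 genes that chance gives, and the 787 over it.

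Between pairs of coatings, citrate minus bPEI ran over the settings above, with no single library left out, from 1 (only the groups compared) to 17 (without both libraries) at 6 h, against 7. At 12 h it ran from 103 (no filter) to 1471 (only the groups compared), against 130, and at 24 h from 9 (minimum mean of 20) to 193 (without both libraries), against 17. PEG minus bPEI ran from 0 to 12 at 6 h (12 without both libraries), from 2 to 15 at 12 h (15 with group variance weights) and from 4 to 58 at 24 h (58 without both libraries), against 0, 2 and 5. Citrate minus PEG ran from 0 to 1 at 6 h, from 0 to 44 at 12 h (44 without both libraries) and from 0 to 5 at 24 h (5 with no filter), against 0, 2 and 1. Leaving out 1 library gave 4 to 13, 11 to 80 and 7 to 22 for citrate minus bPEI, 0 to 11, 1 to 3 and 1 to 13 for PEG minus bPEI, and 0 to 2, 0 to 8 and 0 to 9 for citrate minus PEG. Where these counts were 0, limma with all libraries had 542 genes for PEG minus bPEI at 6 h, and 281, 726 and 465 for citrate minus PEG, at an unadjusted p under 0.05. There edgeR had 3, and 0, 1 and 0. Chance gives a share of 0.05 of the 9324 tested genes at that p, which 281 and 465 did not exceed and 542 and 726 did.

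Of 261 list tests 0 were called with an estimated correlation, against 41 with the preset one. The count was 37 with equal totals, 46 with the block, 37 with fry (24 of the 41 among them), 32 with quantile normalization and 49 without both libraries. At a minimum mean of 20 the correlation of fold changes was 0.68, 0.64 and 0.68 at 6 h for bPEI and PEG, bPEI and citrate, and PEG and citrate. It was 0.62 for bPEI and PEG and 0.76 for PEG and citrate at 12 h, and 0.76, 0.72 and 0.83 at 24 h. bPEI shared 4 calls with each of PEG and citrate at 12 h, against 7.

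Among the values of named genes, 2170 of 2171 kept their direction and 1831 their side of the threshold. The exception was HSPA6 in citrate minus PEG at 6 h, which was not called (0.56, log2) and ran from -0.47 without PEG replicate C to 1.58 without PEG replicate A. In 111 named pairs every treated library lay beyond every control library. For these, leaving out a library or changing the pseudocount could not reverse the direction, so a kept direction there is no test. Side changes numbered 53 of 129 with the spread of only the groups compared and 28 of 129 with group variance weights. A mean over probes of a gene was not run, since the table has 1 value per gene. At the depth and with the 2 controls of 24 h, but without their wider spread, limma recovered 53.1% of simulated 4-fold changes of citrate.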

Other observations

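Of the tests in this part, that of HMOX1 and the count of genes with a single read were chosen only after the result was seen, and no explanation was tested.

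Of the 29 lists tested, 13 were called with no coating at any time. Metallothioneins and zinc or copper handling came closest (lowest camera adjusted p = 0.0535), with 1 of 15 members higher at 12 h with bPEI, MT1G, and 3 adjusted over the list alone. At 12 h with citrate 2 members were lower, at 24 h with bPEI 1 was higher, and in the other 6 comparisons of a coating with NoNP no member was called. MT1G was at 1531 ± 87.3 (SD, n = 3) in NoNP at 6 h, 195 ± 15.4 (SD, n = 3) at 12 h and 4203 ± 1081 (SD, n = 2) at 24 h. At 12 h it was at 437 ± 45.7 with bPEI, 373 ± 93.3 with PEG and 331 ± 79.4 with citrate. Heme oxygenase HMOX1 was at 611 ± 158 in NoNP and 885 ± 30.8 with citrate at 6 h, a difference that was not called. The lowest camera adjusted p was 0.0709 for the unfolded protein response, 0.281 for the interferon response and 0.377 for apoptosis regulators.

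Genes with a single read numbered 453 to 744 (median 640.5) in the 6 libraries of replicates A and B at 6 h, and 119 to 271 (median 192.5) in the other 26. The most frequent read number under 9 was 1 or 2 in the former and 3 to 5 in the latter.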
